A study of Sus scrofa with 17 samples.

How the data were processed

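The data are RNA sequencing counts per gene from the right ventricular myocardium of 17 pigs (Sus scrofa) with right ventricular pressure overload, treated with repeated doses of umbilical cord blood mononuclear cells (n = 7), a single dose (n = 5) or vehicle (n = 5). Replicates are individual animals according to the series text, so the p-values refer to variation among animals. The table holds raw counts of 35670 Ensembl genes per library, which the authors made from reads of an Illumina NextSeq. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.33, HISAT2 2.1.0, SAMtools 1.7 and Subread 1.6.2 with the pig build Sscrofa11.1, while the strand setting and the annotation release are not given in the sources used here. All values were whole numbers. Sex, weight and batch are named as recorded covariates in the series text but are not given per library in the labels, and the doses and time points are not given there either.

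Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 15884 of 35670 genes, and 10374 genes had no count in any library. Libraries were scaled with TMM factors, and 1 model with a coefficient per group was fitted to all 17 libraries with edgeR's quasi-likelihood method and robust spread. The tests were two-sided quasi-likelihood tests with Benjamini-Hochberg adjustment over all genes within each comparison and a threshold of 0.05 on the adjusted p. Log2 fold changes are first group minus second, and their SE was derived from the fold change and the F statistic of the same test. CPM values use the TMM-scaled totals, and log2 CPM values carry a prior count of 2. The median log2 fold change of all genes stayed within 0.1 of 0 under TMM, RLE and upper-quartile scaling.

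In total, 33 gene lists with 887 members were fixed, of which 749 were tested. Each list was tested two-sided with camera of limma 3.58.1 and a preset correlation of 0.01, adjusted by the Benjamini-Hochberg method over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives, where the directional test of fry asks whether the genes of a list move on balance in 1 direction and its mixed test whether they change in either direction. Within each list the p-values of the members were also adjusted over the list alone. Named genes were chosen by a rule. Since no gene passed, these are the 5 genes per direction with the smallest p among genes with a symbol and a mean of at least 1 CPM, members among the 4 with the smallest p of each list described, and NPPA, NPPB, COL1A1, COL3A1, VEGFA and PECAM1 in every comparison. Of the list members only some are described, and 1 further gene that this rule names is not reported here. The groups, tests, lists, naming rule and most alternative settings were chosen before the data were examined. Symbols come from the table, in which 18030 genes have none, and 119 of these were named from the RefSeq annotation of Sscrofa11.1. For 63 genes the symbol differs from that of the reference, and 53 symbols stand on 1319 rows. Positions are those of RefSeq on Sscrofa11.1, matched by symbol.

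Alternatives changed 1 choice at a time, apart from the last that was added after seeing the data. The first were RLE or upper-quartile scaling, no low-count filter or a minimum of 1 CPM in 5 libraries, no robust spread, a fit with only the 2 groups compared, an added fold threshold of 2, DESeq2 1.42.0, and limma-voom with quality weights. Covariates were the library name suffix (_R or none), the first digit of the library name and Y-linked expression. Further fits used a block by replicate number, only libraries with the suffix _R, only M8 and M9 libraries, and each of the 17 libraries left out in turn. Added after seeing the data were a covariate for names beginning with M1, a fit without the 4 libraries under 25000000 counts, thinning of all libraries to the total of the shallowest, and camera with an estimated correlation on the M8 and M9 libraries. Other pseudocounts, which were foreseen for normalised values, did not apply to counts.

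The pipeline was tested on simulated data with known changes drawn from the spread of these libraries. Genes were drawn independently, 200 genes were changed per comparison, and no difference between M1 and other libraries was built in. At a fold of 1.5, 2 and 4, edgeR recovered 17.9%, 62.7% and 95.5% of the changed genes for multidose against control, with 6 false calls among 123. For single dose against control it recovered 4.48%, 52.2% and 84.8%, with 5 false calls among 99, and for multidose against single dose 20.9%, 56.7% and 92.4%, with 5 among 118. DESeq2 made 23, 31 and 34 false calls among 155, 140 and 174, and limma-voom 4, 5 and 5 among 117, 98 and 115. A simulated shift of 0.3 in the oxidative phosphorylation list, with independent genes, was called with the preset correlation (adjusted p = 2.15e-22) and with an estimated one (adjusted p = 5.38e-07), with 0 other lists called. No pair of libraries was a duplicate: the smallest chi-square per degree of freedom among 136 pairs was 21.5.

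Group differences of single values (total counts and the mitochondrial share) were tested with exact two-sided permutation tests over all regroupings, adjusted over 6 tests. For each comparison 99 random regroupings of the libraries were drawn beside the real one and fitted in the same way. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.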

Results

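RNA was sequenced from the right ventricular myocardium of 17 pigs kept under right ventricular pressure overload. Of these animals, 7 had received repeated doses of mononuclear cells from umbilical cord blood (multidose), 5 had received a single dose and 5 had received vehicle (vehicle control). Each library came from a different animal. The libraries held between 21754800 and 61144663 counts. The mean was 34899250 ± 11443176 counts (SD, n = 7) in the multidose group, 42370983 ± 12292975 (SD, n = 5) in the single dose group and 53093598 ± 5562787 (SD, n = 5) in the vehicle controls. Multidose libraries differed from control libraries by -18194347 counts on average (exact two-sided permutation p = 0.0101 over 792 regroupings, adjusted p = 0.0606 over 6 tests). Mitochondrially encoded genes took 18.98% ± 2.38 of the counts in the multidose group (SD, n = 7), 18.8% ± 1.91 in the single dose group (SD, n = 5) and 15.8% ± 2.88 in the controls (SD, n = 5). The difference of 3.19 percentage points between multidose and control had an exact two-sided permutation p of 0.0669 (adjusted p = 0.155), and that of 3.001 points between single dose and control had p = 0.103 (adjusted p = 0.155). A total of 15884 genes had enough counts to be tested.

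The largest differences among the libraries followed the library names in the labels and not the dosing groups. The names of 5 libraries begin with M1 (multidose 1, 2, 3 and 4 and single dose 1). Those of the other 12, every control among them, begin with M8 or M9, and the labels do not say what the names stand for. On the first principal component, which held 26.7% of the variance, the M1 libraries scored between -62.8 and -37.1 and the others between 0.107 and 38.1. In a comparison chosen after the data were seen, 3783 genes differed between the M1 libraries and the others (1733 higher, 2050 lower, adjusted p under 0.05), and 666 differed between the 4 M1 and the 3 other libraries within the multidose group alone. MYH15 (ENSSSCG00000022175), a myosin heavy chain gene, was higher in the M1 libraries by 4.40 (SE 0.30) on the log2 scale, at 8.62 ± 4.73 CPM (SD, n = 5) against 0.406 ± 0.161 CPM (SD, n = 12). NPPA (ENSSSCG00000061442, chromosome 6, 71919557 to 71921345), which encodes atrial natriuretic peptide, fell by 3.94 on the log2 scale (SE 0.60, adjusted p = 0.000390 by edgeR) in the M1 libraries. NPPB (ENSSSCG00000003431, chromosome 6, 71930374 to 71931843), which encodes brain natriuretic peptide, fell by 3.45 (SE 0.74, adjusted p = 0.00365 by edgeR). Of the fixed gene lists, 34 of 40 cytoplasmic ribosomal protein genes and 28 of 53 nuclear oxidative phosphorylation genes rose in the M1 libraries and none of either list fell. In the same comparison 10 of 20 natriuretic and cardiac stress genes and 13 of 31 T and natural killer cell markers fell, while 0 and 2 rose. Of 18 fibroblast markers 8 rose and 1 fell. Over all 15884 genes 1733 rose and 2050 fell. By camera these 5 lists passed with the preset correlation (adjusted p = 1.82e-18 for the ribosomal list and 4.13e-12 for oxidative phosphorylation). So did Schwann and neural markers, of which 2 of 13 rose and 0 fell (median 0.71, adjusted p = 0.0481). With an estimated correlation 0 of the 33 lists passed (adjusted p = 0.978 for each).

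**Figure D1:**
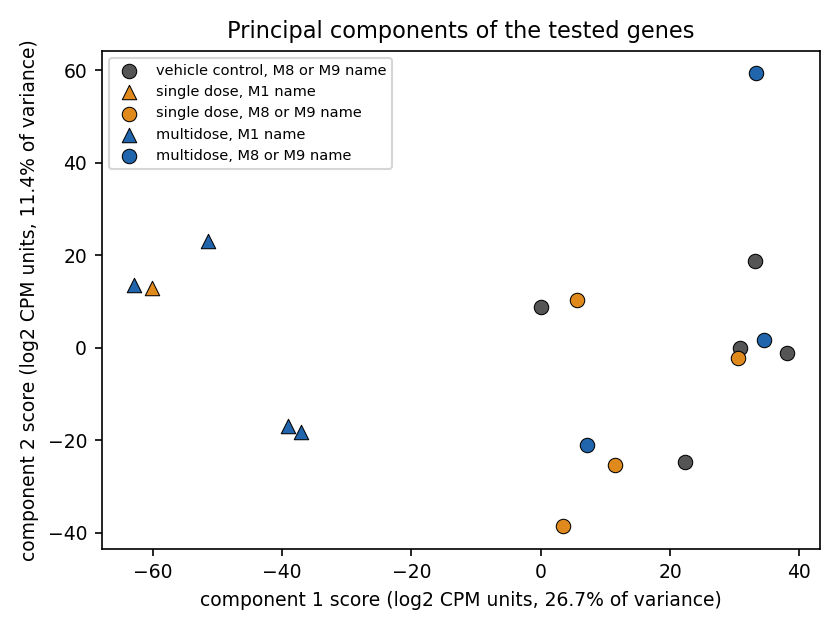
Each point is 1 library, placed by its scores on the first component (x axis, 26.7% of the variance) and the second (y axis, 11.4% of the variance), both in log2 CPM units, with colour for the dosing group and triangles for M1 names. The 5 M1 libraries lie between -62.8 and -37.1 on the x axis and the other 12 between 0.107 and 38.1.

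The comparison of multidose with vehicle control asks how repeated cell doses change expression in the pressure-loaded ventricle. TSPOAP1 (ENSSSCG00000017638, chromosome 12, 34578698 to 34606623), which encodes a binding partner of the mitochondrial translocator protein, had the smallest p, at 3.23 ± 1.07 CPM (SD, n = 7) after multiple doses against 0.836 ± 0.390 CPM (SD, n = 5) in controls. Its log2 fold change was 1.94 (SE 0.34, adjusted p = 0.355 by edgeR), and 1.91 in the M8 and M9 libraries alone. SIK1 (ENSSSCG00000035037, chromosome 13, 206454695 to 206465802), a salt-inducible kinase gene, measured 12.6 ± 5.07 CPM (SD, n = 7) against 42.1 ± 35.9 CPM (SD, n = 5). Its log2 fold change was -1.73 (SE 0.39), and vehicle control 4 alone measured 104 CPM. The other genes with the smallest p among positive values were AS3MT (ENSSSCG00000010592, 0.58, SE 0.13), an arsenic methyltransferase gene, and the histone gene H2AJ (ENSSSCG00000039307, 0.57, SE 0.14). They were followed by TMEM98 (ENSSSCG00000017727, 0.90, SE 0.22, and 0.43 without the M1 libraries) and MRPS23 (ENSSSCG00000035193, 0.48, SE 0.12), a mitochondrial ribosome gene. On the negative side stood DLG5 (ENSSSCG00000026268, -0.83, SE 0.18), a cell polarity scaffold, and the adhesion receptor ADGRG1 (ENSSSCG00000002815, -0.75, SE 0.16). The same side held SLC4A11 (ENSSSCG00000007157, -0.83, SE 0.20), a membrane transporter, and STUM (ENSSSCG00000024288, -1.10, SE 0.26). None of these genes passed, with an adjusted p of 0.366 by edgeR for each apart from TSPOAP1.

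By edgeR, 0 of 15884 genes changed between multidose and control, with 1997 genes at an unadjusted p under 0.05 (1071 positive, 926 negative) where 794.2 would be expected by chance. That count was 592 without the M1 libraries, 591 with the first digit of the library name as a covariate and 606 with the M1 name as one. It was 498 without the 4 libraries under 25000000 counts, which are all M1 libraries (multidose 1, 2 and 3 and single dose 1). That fit therefore does not separate depth from the names. With all libraries thinned to the shallowest total the count was 1888. DESeq2 called 8 genes, among them TSPOAP1 (adjusted p = 5.54e-05), SIK1, ADGRG1, DLG5, AS3MT and the chemokine gene CXCL10 (-2.33), the last 5 each at an adjusted p of 0.0452. The tools differed most for CXCL10, which had an adjusted p of 0.948 by edgeR, against 0.366 for SIK1, ADGRG1, DLG5 and AS3MT. By limma-voom 0 genes passed. In data simulated from these libraries edgeR recovered 62.7% of 67 genes changed by a fold of 2 at these group sizes, and DESeq2 made 23 false calls among 155. The simulation had independent genes, 200 changed genes and no M1 difference, so recovery in the real data may be lower.

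NPPA measured 971 ± 1560.5 CPM (SD, n = 7) after multiple doses and 2385 ± 1756 CPM (SD, n = 5) in controls, a log2 fold change of -1.30 (SE 0.91, adjusted p = 0.540 by edgeR) that stood at -0.19 without the M1 libraries. NPPB measured 745 ± 868 CPM (SD, n = 7) against 2192 ± 1692 CPM (SD, n = 5), a log2 fold change of -1.56 (SE 0.92, adjusted p = 0.474 by edgeR), and -0.57 without those libraries. The collagen gene COL3A1 (ENSSSCG00000016034) had a value of 0.50 (SE 0.33) that turned to -0.28 without the M1 libraries, and COL1A1 (ENSSSCG00000036135) a value of -0.29 (SE 0.24). VEGFA (ENSSSCG00000001695), the vascular growth factor, had a value of -0.34 (SE 0.22) and PECAM1 (ENSSSCG00000017277), an endothelial adhesion gene, a value of 0.00 (SE 0.16), negative without the M1 libraries (-0.25).

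**Figure D2:**
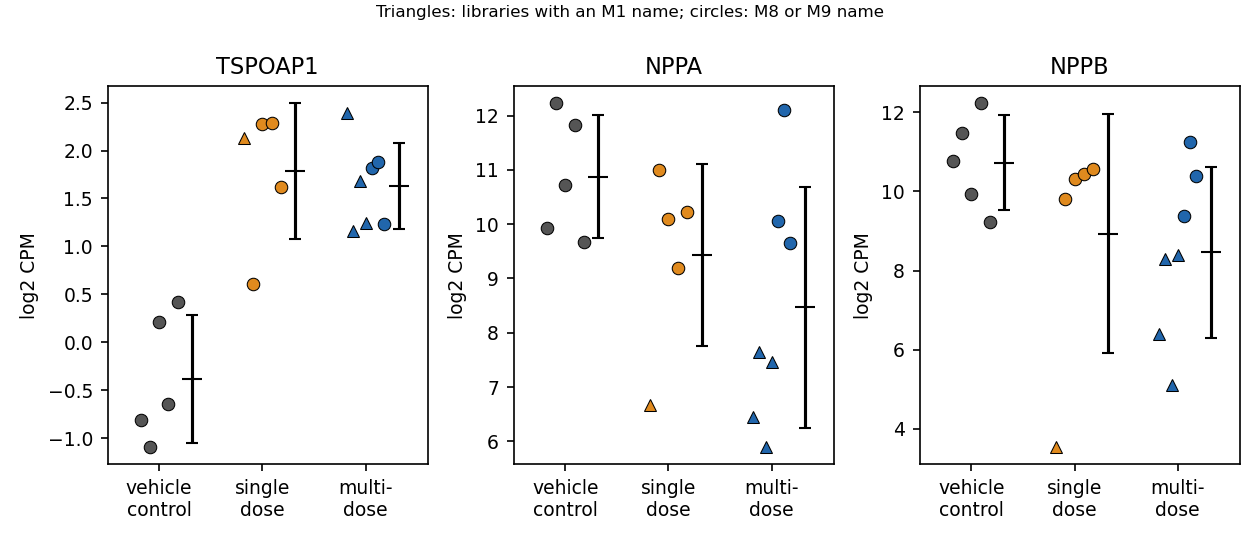
Expression of TSPOAP1, NPPA and NPPB (y axes, log2 CPM) in each library by dosing group (x axes), with triangles for M1 names, circles for M8 or M9 names, and a bar for the mean and SD of the log2 values of each group. TSPOAP1 lay between 1.53 and 5.25 CPM in the 12 dosed libraries and between 0.47 and 1.34 CPM in the controls.

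Oxidative phosphorylation and ribosomal protein genes were positive throughout after multiple doses. All 53 nuclear oxidative phosphorylation genes had positive values, among them ATP5PF (ENSSSCG00000038399, 0.69, SE 0.21), an ATP synthase subunit, and COX6C (ENSSSCG00000060790, 0.73, SE 0.24), a cytochrome oxidase subunit. Their median was 0.33 (adjusted p = 1.45e-17, and adjusted p = 0.700 with an estimated correlation), and 0.17 without the M1 libraries, where ATP5PF stood at 0.32 and COX6C at 0.47. All 13 mitochondrially encoded genes were positive as well, with 0.67 (SE 0.28) for ND3 (ENSSSCG00000018084). The mitochondrially encoded median was 0.39 (adjusted p = 1.04e-05, and adjusted p = 0.700 with an estimated correlation). The 40 cytoplasmic ribosomal protein genes were all positive, with 0.81 (SE 0.28) for RPS24 (ENSSSCG00000039544) and 0.92 (SE 0.32) for RPL22 (ENSSSCG00000054047). The ribosomal median was 0.49 (adjusted p = 4.53e-13, and adjusted p = 0.700 with an estimated correlation). In the M1 libraries against the others 34 of the 40 rose, and without the M1 libraries the ribosomal median was -0.02 (adjusted p = 0.164). Cell cycle genes were positive in 22 of 29 cases, led by the kinase gene AURKB (ENSSSCG00000028924, 0.57, SE 0.26) and the cyclin gene CCNB1 (ENSSSCG00000029326, 1.01, SE 0.49). The cell cycle median was 0.24 (adjusted p = 0.00869, and adjusted p = 0.773 with an estimated correlation). The cell cycle call ended without vehicle control 2 (adjusted p = 0.0730), vehicle control 4 (0.418) or multidose 7 (0.0509). Without the M1 libraries the median was -0.0018 (adjusted p = 0.146), with AURKB at 0.21 and CCNB1 at 0.44. Sarcomere and Z-disc genes were positive in 19 of 27 cases, led by MYL3 (ENSSSCG00000011325, 0.50, SE 0.16), the ventricular light chain, and the troponin gene TNNC1 (ENSSSCG00000011441, 0.54, SE 0.21). The sarcomere median was 0.12 (adjusted p = 0.0473, and adjusted p = 0.773 with an estimated correlation). That call was kept in 7 of the 17 fits that left out 1 library (adjusted p from 0.00467 to 0.418). No member of these 5 lists passed over all genes tested (0), and 0 passed adjusted over the list alone.

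T and natural killer cell markers and immediate early genes lay on the other side. Of 31 T and natural killer cell markers 28 were negative, with a median of -0.61 (adjusted p = 1.04e-05, and adjusted p = 0.700 with an estimated correlation). They included CD8A (ENSSSCG00000008217, -1.33, SE 0.35), a coreceptor of cytotoxic T cells, and the T cell receptor component CD3E (ENSSSCG00000040140, -1.15, SE 0.37). Over all genes 0 of them passed, and adjusted over the list alone 1 did, CD8A. The median was -0.31 and CD3E stood at -0.59 without the M1 libraries. In the M1 libraries against the others, 13 of these markers fell. Immediate early genes were negative in 26 of 29 cases, with a median of -0.39 (adjusted p = 1.84e-05, and adjusted p = 0.700 with an estimated correlation). Among these 0 passed over all genes and 5 passed adjusted over the list alone, namely EGR2, ZFP36, CEBPD, FOSL2 and KLF2. Values were -0.78 (SE 0.23) for FOSL2 (ENSSSCG00000032527) and -1.44 (SE 0.43) for CEBPD (ENSSSCG00000032367). Angiogenesis genes were negative in 21 of 29 cases, with a median of -0.30 (adjusted p = 0.00869, and adjusted p = 0.700 with an estimated correlation). Of these 0 passed over all genes and 1 passed adjusted over the list alone, the Notch receptor gene NOTCH4 (ENSSSCG00000001440, -0.81, SE 0.20). The angiogenesis call ended without multidose 5 (adjusted p = 0.0834) or vehicle control 1 (0.148). Natriuretic and fetal cardiac stress genes were negative in 16 of 20 cases, with a median of -0.32 (adjusted p = 0.0127, and adjusted p = 0.773 with an estimated correlation). They included XIRP1 (ENSSSCG00000034015, -0.65, SE 0.35) and MYOT (ENSSSCG00000014324, -0.47, SE 0.26), which encode actin-binding muscle proteins. The natriuretic median was -0.05 (adjusted p = 0.810) and XIRP1 stood at -0.02 without the M1 libraries. In the M1 libraries against the others, 10 of the 20 fell. The natriuretic call ended without vehicle control 2 (adjusted p = 0.148) or vehicle control 4 (0.0689). Endothelial markers were negative in 19 of 25 cases, with a median of -0.18 (adjusted p = 0.0473, and adjusted p = 0.773 with an estimated correlation) and with -0.56 (SE 0.22) for BTNL9 (ENSSSCG00000028567). The endothelial call was kept in 8 of the 17 fits that left out 1 library (adjusted p from 0.00288 to 0.391). For the natriuretic and endothelial lists 0 genes passed over all genes and 0 adjusted over the list alone. In all, 10 of 33 lists passed with the preset correlation and 0 with an estimated correlation. Of these 10, 7 passed in the same direction without the M1 libraries.

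The comparison of single dose with vehicle control asks what 1 dose of cells changes. TSPOAP1 again had the smallest p, at 3.74 ± 1.44 CPM (SD, n = 5) against 0.836 ± 0.390 CPM (SD, n = 5), a log2 fold change of 2.15 (SE 0.36, adjusted p = 0.185 by edgeR). It passed without single dose 2 (2.36, adjusted p = 0.0247 by edgeR). It also passed with a covariate for Y-linked expression (adjusted p = 0.0325 by edgeR) or after thinning all libraries to the shallowest total (adjusted p = 0.0308 by edgeR). NPR1 (ENSSSCG00000006572, chromosome 4, 95957220 to 95974253), which encodes the receptor of the natriuretic peptides, measured 20.4 ± 3.71 CPM (SD, n = 5) against 34.7 ± 8.87 CPM (SD, n = 5). Its log2 fold change was -0.77 (SE 0.17). CRYM (ENSSSCG00000007849, chromosome 3, 24815010 to 24835837), which encodes a thyroid hormone-binding protein, had a log2 fold change of 3.97 (SE 1.01). It measured 17.7 CPM in single dose 4 and 0.331 CPM in single dose 5. Other positive values were those of IFT46 (ENSSSCG00000029649, 0.41, SE 0.09), a gene of ciliary transport, and SOSTDC1 (ENSSSCG00000021126, 2.27, SE 0.56), a BMP and Wnt antagonist that measured 5.11 CPM in single dose 1 and stood at 1.51 without it. Other negative values were those of the transcription factor gene ZBTB16 (ENSSSCG00000030095, -1.64, SE 0.38) and the granzyme inhibitor gene SERPINB9 (ENSSSCG00000031615, -0.57, SE 0.13). They were joined by PEAR1 (ENSSSCG00000006463, -0.75, SE 0.18), a platelet and endothelial receptor gene, and GALNT15 (ENSSSCG00000011195, -2.83, SE 0.68), a glycosylation enzyme gene that measured 74.1 CPM in vehicle control 4 and stood at -1.28 without it. ZBTB16 was also highest in vehicle control 4, at 6.61 log2 CPM against 4.40 to 5.45 in the other controls. Each of these genes apart from TSPOAP1 had an adjusted p of 0.755 by edgeR. NPPA had a log2 fold change of -1.24 (SE 1.01) and NPPB one of -1.11 (SE 1.01), each with an adjusted p of 0.891 by edgeR. COL3A1 stood at 0.41 (SE 0.36), COL1A1 at 0.052 (SE 0.26), VEGFA at -0.15 (SE 0.23) and PECAM1 at -0.11 (SE 0.17), with adjusted p between 0.891 and 0.981 by edgeR. NPPB measured 11.6 CPM in single dose 1, the M1 library of this group.

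By edgeR, 0 of 15884 genes changed between single dose and control, with 836 at an unadjusted p under 0.05 (385 positive, 451 negative). DESeq2 called 10 genes, including TSPOAP1 (2.16, adjusted p = 1.77e-05), RASGEF1A (2.81, adjusted p = 0.0101), ZBTB16 and FKBP5, a glucocorticoid-induced chaperone gene (-1.80, adjusted p = 0.0406). Its calls also held IFT46, GALNT15 and CRYM (adjusted p = 0.0446 each) and SOSTDC1 and NPR1 (adjusted p = 0.0468 each). FKBP5 measured 274.7 CPM in vehicle control 4 and 47.65 to 66.58 CPM in the other controls. By limma-voom 0 genes passed. Leaving out single dose 5 gave a call for ACSM5 (ENSSSCG00000026453), a fatty acid activation gene chosen after its values were seen, at 7.24 on the log2 scale (adjusted p = 0.00173 by edgeR). In single dose 2, 3 and 4 it measured 7.87, 10.6 and 6.93 CPM, but in single dose 1 it measured 0.276 and in single dose 5 0.0184 CPM. In the simulated data edgeR recovered 52.2% of 67 genes changed by a fold of 2 at these group sizes.

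Oxidative phosphorylation genes were on the positive side after a single dose as well. All 53 nuclear oxidative phosphorylation genes were positive, with a median of 0.27 (adjusted p = 3.38e-10, and adjusted p = 0.682 with an estimated correlation). Among them were ATP5PO (ENSSSCG00000012042, 0.38, SE 0.22) and NDUFA9 (ENSSSCG00000000719, 0.34, SE 0.20). Without single dose 1, the M1 library, the M8 and M9 libraries gave a median of 0.16. The 13 mitochondrially encoded genes were all positive, with a median of 0.31 (adjusted p = 3.25e-05, and adjusted p = 0.682 with an estimated correlation), and 0.40 (SE 0.23) for ND1 (ENSSSCG00000018065). Cytoplasmic ribosomal protein genes were positive in 38 of 40 cases, with a median of 0.25 (adjusted p = 7.21e-06, and adjusted p = 0.720 with an estimated correlation). Without the M1 library the median was 0.09, and the call ended without vehicle control 3 (adjusted p = 0.448). Among ribosomal genes RPL22 stood at 0.47 (SE 0.33) and RPS9 (ENSSSCG00000029785) at 0.30 (SE 0.22), both of which turned negative among the libraries with the suffix _R. Skeletal muscle genes were positive in 6 of 8 cases, with a median of 0.31 (adjusted p = 0.0382, and adjusted p = 0.628 with an estimated correlation). They included the light chain gene MYL1 (ENSSSCG00000016157, 1.69, SE 0.62) and MYBPC2 (ENSSSCG00000003218, 1.12, SE 0.45). Cell cycle genes were positive in 20 of 29 cases, with a median of 0.25 (adjusted p = 0.0412, and adjusted p = 0.831 with an estimated correlation) and with 0.59 (SE 0.27) for AURKB. In the 17 fits that left out 1 library, the skeletal muscle call was kept in 9, with an adjusted p of up to 0.122, and the cell cycle call in 11, with an adjusted p of up to 0.783. Without the M1 libraries both ended (adjusted p = 0.0781 and 0.0920). Of these 5 lists 0 genes passed over all genes and 0 passed adjusted over the list alone.

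Vascular genes lay on the negative side after a single dose. Angiogenesis genes were negative in 23 of 29 cases, with a median of -0.24 (adjusted p = 0.000368, and adjusted p = 0.682 with an estimated correlation). They were led by FLT1 (ENSSSCG00000009320, -0.82, SE 0.21), a VEGF receptor gene, and NOTCH4 (-0.66, SE 0.22). Over all genes 0 passed, and adjusted over the list alone 1 did, FLT1. Endothelial markers were negative in 19 of 25 cases, with a median of -0.11 (adjusted p = 0.00677, and adjusted p = 0.682 with an estimated correlation). Of them 0 passed over all genes and 1 adjusted over the list alone, BTNL9 (-0.89, SE 0.24). The endothelial call ended without vehicle control 1 (adjusted p = 0.178) or single dose 4 (0.0554). Natriuretic and fetal cardiac stress genes were negative in 16 of 20 cases, with a median of -0.41 (adjusted p = 0.00677, and adjusted p = 0.682 with an estimated correlation). The smallest p were those of XIRP1 (-0.77, SE 0.38) and MYOT (-0.56, SE 0.28). That call ended without single dose 1, the M1 library (adjusted p = 0.199), or vehicle control 2 (0.108). In the M8 and M9 libraries alone the natriuretic median was -0.18 (adjusted p = 0.112). Heat shock and unfolded protein response genes were negative in 24 of 30 cases, with a median of -0.21 (adjusted p = 0.00941, and adjusted p = 0.682 with an estimated correlation). Values were -0.90 (SE 0.27) for the chaperone gene HSPH1 (ENSSSCG00000009334) and, opposite in sign, 0.83 (SE 0.25) for ASNS (ENSSSCG00000015340), the asparagine synthetase gene. The heat shock call ended without vehicle control 4 (adjusted p = 0.514) or vehicle control 5 (0.0969). Immediate early genes were negative in 20 of 29 cases, with a median of -0.24 (adjusted p = 0.0119, and adjusted p = 0.682 with an estimated correlation), led by CEBPD (-1.52, SE 0.48, and -0.66 without vehicle control 4). It ended without vehicle control 1 (adjusted p = 0.0767), vehicle control 4 (0.541), single dose 2 (0.0961) or single dose 3 (0.0860). Apoptosis and cell survival genes were negative in 19 of 26 cases, with a median of -0.13 (adjusted p = 0.0444, and adjusted p = 0.682 with an estimated correlation). They were led by the survival genes MCL1 (ENSSSCG00000039314, -0.35, SE 0.15) and BCL2L1 (ENSSSCG00000035357, -0.68, SE 0.29). It was kept in 11 of the 17 fits that left out 1 library, with an adjusted p of up to 0.353. For the natriuretic, heat shock, immediate early and apoptosis lists 0 genes passed over all genes and 0 adjusted over the list alone. In all, 11 of 33 lists passed with the preset correlation and 0 with an estimated correlation. Of these 11, 8 passed in the same direction without the M1 libraries.

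**Figure D3:**
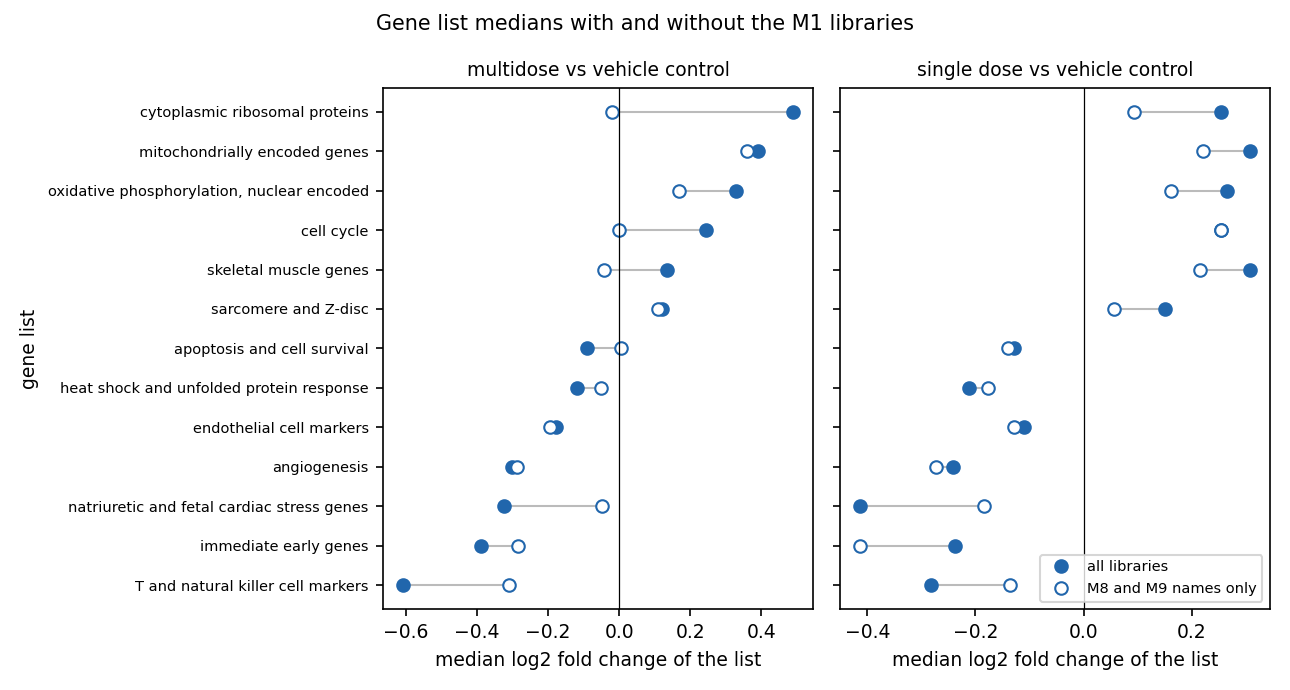
Median log2 fold change (x axes) of each gene list (y axis) that passed with the preset correlation in at least 1 of the comparisons with vehicle control, from all libraries (filled points) and from the M8 and M9 libraries alone (open points). The ribosomal median after multiple doses is 0.49 with all libraries and -0.02 without the M1 libraries, and that of nuclear oxidative phosphorylation 0.33 and 0.17.

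The comparison of multidose with single dose asks whether repeating the dose changes expression. The genes with the smallest p among positive values were NR1D2 (ENSSSCG00000027017, chromosome 13, 10756954 to 10791219), a nuclear receptor of the circadian clock, with a log2 fold change of 0.55 (SE 0.17), and GINS3 (ENSSSCG00000002802, 0.50, SE 0.18), a DNA replication gene. They were followed by LONRF1 (ENSSSCG00000006968, 0.59, SE 0.21), HECTD2 (ENSSSCG00000020912, 0.55, SE 0.20), a ubiquitin ligase gene, and GPAT3 (ENSSSCG00000009233, 0.50, SE 0.18), a gene of triglyceride synthesis. NR1D2 measured 88.3 ± 19.9 CPM (SD, n = 7) after multiple doses and 60.4 ± 9.09 CPM (SD, n = 5) after 1 dose. Without the M1 libraries NR1D2 stood at 0.17, HECTD2 at 0.36 and GPAT3 at 0.27. Negative values were led by TUB (ENSSSCG00000014581, -0.75, SE 0.23), PEX5L (ENSSSCG00000011766, -1.01, SE 0.31), the olfactory receptor gene OR51E1 (ENSSSCG00000014766, -0.96, SE 0.30), SEZ6 (ENSSSCG00000035445, -0.75, SE 0.25) and the ciliary gene NPHP4 (ENSSSCG00000029843, -0.59, SE 0.20). NPPA differed by -0.05 (SE 0.92), NPPB by -0.44 (SE 0.92) and COL3A1 by 0.09 (SE 0.33), and all 3 changed sign without the M1 libraries, to 0.77, 0.23 and -0.39. PECAM1 stood at 0.11 (SE 0.16), and at -0.10 without the M1 libraries, COL1A1 at -0.34 (SE 0.24) and VEGFA at -0.19 (SE 0.22). None of these genes passed, with an adjusted p of 0.99998 by edgeR for each.

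By edgeR, 0 of 15884 genes changed between the dosed groups, with 335 at an unadjusted p under 0.05 (141 positive, 194 negative), and DESeq2 and limma-voom called 0 each. Leaving out single dose 5 gave 1 call, ACSM5 (-6.53, adjusted p = 0.000857 by edgeR), which the 3 single dose libraries named above carry.

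Interferon-induced genes stood apart between the dosed groups, and their direction rested on 1 library. All 29 genes of the type I interferon response were positive, with a median of 0.52 (adjusted p = 0.00741, and adjusted p = 0.926 with an estimated correlation). Values were 2.93 (SE 1.26) for ISG15 (ENSSSCG00000040575), a ubiquitin-like antiviral protein, and 1.91 (SE 0.90) for IRF7 (ENSSSCG00000012853). ISG15 measured 1632 CPM in multidose 5, 91.6 CPM in single dose 1 and 44.5 CPM in vehicle control 1. Without multidose 5 the list turned negative (adjusted p = 0.0806), with ISG15 at -0.65. The interferon call also ended without single dose 2 (adjusted p = 0.0573), single dose 4 (0.126) or single dose 5 (0.105). Without the M1 libraries, a fit that keeps multidose 5, the interferon median was 1.65 (adjusted p = 8.50e-22, and adjusted p = 0.881 with an estimated correlation). T and natural killer cell markers were negative in 24 of 31 cases, with a median of -0.34 (adjusted p = 0.000124, and adjusted p = 0.926 with an estimated correlation). They were led by the T cell genes CD6 (ENSSSCG00000013111, -1.24, SE 0.46) and CD3E (-0.97, SE 0.37), and without the M1 libraries the median was -0.27 and the call ended (adjusted p = 0.152). Ribosomal protein genes were positive in 39 of 40 cases, with a median of 0.22 (adjusted p = 1.04e-05, and adjusted p = 0.926 with an estimated correlation) and 0.46 (SE 0.28) for RPS24. The ribosomal median turned to -0.10 without the M1 libraries (adjusted p = 0.400). Nuclear oxidative phosphorylation genes were positive in 49 of 53 cases, with a median of 0.09 (adjusted p = 1.30e-05, and adjusted p = 0.926 with an estimated correlation) and 0.37 (SE 0.24) for COX6C. The oxidative phosphorylation call ended without single dose 4 (adjusted p = 0.919) or without the M1 libraries (median 0.03, adjusted p = 0.186). Fatty acid oxidation genes were positive in 24 of 34 cases, with a median of 0.10 (adjusted p = 0.0384, and adjusted p = 0.926 with an estimated correlation). The smallest p were those of LPL (ENSSSCG00000040631, 0.39, SE 0.21), which encodes lipoprotein lipase, and HADHA (ENSSSCG00000008571, 0.29, SE 0.17). That call was kept in 9 of the 17 fits that left out 1 library, with an adjusted p of up to 0.268. Immediate early genes were negative in 21 of 29 cases, with a median of -0.13 (adjusted p = 0.00990, and adjusted p = 0.926 with an estimated correlation). They were led by EGR3 (ENSSSCG00000009630, -0.97, SE 0.38), NR4A1 (ENSSSCG00000031321, -0.84, SE 0.33) and FOSB (ENSSSCG00000031616, -1.41, SE 0.58). The immediate early call ended without single dose 1 (adjusted p = 0.660), and without all M1 libraries the list turned positive (median 0.06), as did NR4A1 (0.06) and FOSB (0.29). Of these 6 lists 0 genes passed over all genes, 0 passed adjusted over the list alone, and 2 of the 6 list calls passed in the same direction without the M1 libraries.

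A test for any difference among the 3 groups gave 0 genes by edgeR (smallest adjusted p = 0.463, 1068 genes at an unadjusted p under 0.05), 9 by DESeq2 and 0 by limma-voom. Across 15884 genes, which are not independent replicates, the log2 fold changes of the 2 dosed groups against control had a correlation of 0.715, and 78.8% had the same sign. Both comparisons share their controls, which alone gave a correlation of 0.535 (range 0.512 to 0.557) in 50 simulations of unchanged groups. These simulations drew genes independently and had no M1 difference. Their range therefore leaves out differences among libraries that many genes share, and cannot show whether 0.715 lies beyond shared controls. With the controls split so that each dosed group had its own, the correlation was 0.262 on average over 10 splits (range 0.111 to 0.364) and 59.4% of genes had the same sign. M1 libraries are in both dosed groups (4 in multidose and 1 in single dose) and 0 are controls. How far they carry the correlation that is left was not tested. TSPOAP1 was the gene with the smallest p in both comparisons with control, and all 12 dosed libraries lay above all 5 controls. In a count chosen after this was seen, 6 of 15884 genes had all dosed libraries above all controls (RASGEF1A, AS3MT, TSPOAP1, IFT46, ERG28 and ERICH4) and 4 had all below, where chance gives 2.57 genes (0.0162%) each way.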

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

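The comparison of the M1 libraries with the others, the tests on circadian clock, glucocorticoid and heart maturity genes, the tests of whether the M1 libraries explain single gene lists, which read a planned fit without them, and the estimated correlation in that fit were chosen only after the results they concern had been seen.

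The values in this paragraph lay far from the rest of their group by Dixon's test at the 95% level, which flags about 1 in 20 groups by chance: 14 of 204 groups were picked out where 10.2 would be expected. Values are mean log2 CPM of a list or log2 CPM of a gene. Natriuretic and fetal cardiac stress genes measured 7.58 in single dose 1, with a median of 8.82 in the rest of its group. Type I interferon response genes measured 7.20 in multidose 5 (median of the rest 4.31) and 5.53 in single dose 1 (4.09). Antigen presentation genes measured 6.55 in multidose 5 (5.004). Schwann and neural markers measured 0.40 in single dose 4 (1.41), and atrial and conduction genes 2.51 in single dose 1 (3.02). Sarcomere and Z-disc genes measured 9.80 in multidose 4 (10.10), apoptosis and cell survival genes 4.87 in vehicle control 4 (4.57), and ribosomal protein genes 7.72 in vehicle control 3 (8.84). Among genes, NPPB measured 3.55 in single dose 1 (10.37) and H2AJ 4.95 in multidose 5 (4.38). SOSTDC1 measured -1.44 in multidose 6 (0.01). HECTD2 measured 4.38 in multidose 1 (3.40) and GPAT3 5.17 in single dose 3 (4.50).

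Other splits of the libraries were drawn for each count, 100 in all with the real one. For the counts of 0 genes by edgeR, all 100 splits gave at least as many, as any split must, so these counts say nothing about chance: multidose against control (1997 genes at an unadjusted p under 0.05, 8 calls by DESeq2 and 0 by limma-voom; highest other split 1159 genes), single dose against control (836, 10 and 0; highest other 7), multidose against single dose (335, 0 and 0; highest other 169) and any difference among the 3 groups (1068, 9 and 0; highest other 184). For the genes at an unadjusted p under 0.05, chance could not be excluded: 11 splits reached 1997 for multidose against control (highest other 4301), 27 reached 836 for single dose against control (highest other 1993), and 87 reached 335 for multidose against single dose (highest other 3476). The split with 1159 genes put 4 M1 libraries in the group of 5 and 0 in the group of 7. The split with 169 genes put all 5 in the first group. The layout of the split with 1159 genes does not give such a count by itself, since another split with that layout gave 13 genes. The real multidose and control groups have a different layout, with 4 in the group of 7 and 0 in the group of 5. They gave 0 genes by edgeR, and another split with the real layout gave 10.

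The 5 M1 libraries differed from the other 12 in 3783 genes, and 1 of 100 splits into groups of these sizes, the real one, reached that count (highest other 40). Because the grouping by M1 names was chosen after the data were seen, these splits cannot exclude chance. Sequencing depth and the _R suffix are argued against as the whole cause, since 91.5% of these genes still passed after all libraries were thinned to 1 total and 72.9% with the suffix as a covariate. Repeated dosing is argued against as the whole cause as well, since 666 genes differed between M1 and other libraries within the multidose group. With the dosing group as a covariate 55.6% of the 3783 genes still passed, and within the multidose group, with fewer libraries, 16.7% did. A part that goes with dosing stays open. The genomic span of the genes had a rho of 0.0692 with the fold change. Span includes introns and is not the length of the transcript, so a bias with transcript length stays open. Older or more mature animals may differ in this way, but the lists of immature and mature heart genes did not decide it (larger adjusted p = 0.854 with an estimated correlation). A batch, a cohort of animals or a harvest time that goes with the names stays open and cannot be told apart, because the labels do not explain the names, and GC content was not tested.

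Of the 21 list calls against control with the preset correlation, 15 were kept in direction and call without the M1 libraries, so how far these libraries contribute to the set as a whole stays open. For oxidative phosphorylation the M1 libraries are argued against as the whole cause by the preset correlation only. Both comparisons with control still passed without them (larger adjusted p = 5.74e-05, and 0.739 with an estimated one), although the median after multiple doses went from 0.33 to 0.17. Among the M8 and M9 libraries the mean log2 CPM of the list overlapped between groups. It was 8.36 to 8.57 in multidose, 8.01 to 8.65 in single dose and 7.78 to 8.55 in controls, lowest in vehicle control 3. A fit without both the M1 libraries and vehicle control 3 was not run. For the ribosomal and natriuretic lists after multiple doses the M1 libraries are a candidate explanation, since the medians without them were -0.019 and -0.050. Sex of the animals is argued against as the whole cause, with 17 of the 21 calls kept when Y-linked expression was a covariate. The biological explanation, an effect of the cells, stays open, since none of these 21 calls held with an estimated correlation.

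FKBP5, PER1 and SIK1, which respond to glucocorticoids, clock or cyclic AMP signals, had their highest values in vehicle control 4, at 274.7, 183 and 104 CPM. Vehicle control 4 alone stays open as a cause. Taking out PER1, FKBP5, ZBTB16 and CEBPD, whose fall had been seen, left 13 glucocorticoid targets. These are not independent of the data, since PDK4, DUSP1, NFKBIA, CDKN1A, ANGPTL4 and MT1A also belong to fixed lists tested here. Without vehicle control 4 their medians were still negative in both dosed groups (-0.21 after multiple doses and -0.23 after a single dose, against -0.49 and -0.68 with it). With an estimated correlation the 13 targets then passed after a single dose (adjusted p = 0.0290, and 0.0586 with vehicle control 4) but not after multiple doses (0.192). Glucocorticoid exposure may differ between the groups, with all 13 of these targets negative in both, but the larger adjusted p was 0.171 with an estimated correlation. Time of day at harvest might also differ, and the 15 clock genes not seen before did not decide it (smaller adjusted p = 0.148 by the mixed test of fry), with 12 negative after a single dose (median -0.18, adjusted p = 0.108 with an estimated correlation, and 0.0290 without vehicle control 4) and 9 after multiple doses (-0.12, adjusted p = 0.611, and 0.397 without it). None of these can be told apart with the labels at hand, which give no harvest time, and an effect of the cells on these genes was not tested separately.

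With members seen before left in, 3 of the 4 lists written for this part passed after a single dose with an estimated correlation. They were glucocorticoid targets (17 of 17 negative, median -0.69, adjusted p = 0.0223), clock genes (15 of 18, -0.20, adjusted p = 0.0188) and immature heart genes (10 of 11, -0.32, adjusted p = 0.0223). The glucocorticoid and clock lists hold members whose fall had been seen when the lists were written. After multiple doses 0 of the 4 passed with an estimated correlation (smallest adjusted p = 0.113). The glucocorticoid (adjusted p = 4.37e-06) and mature heart (0.000392) lists passed there with the preset correlation, and the glucocorticoid and clock lists by the mixed test of fry (adjusted p = 0.0291 each). After a single dose all 4 passed with the preset correlation (largest adjusted p = 0.0177), and the glucocorticoid and clock lists by the mixed test of fry (0.0142 and 0.0375).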

How the results depend on the processing

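Chosen after seeing the data were the M1 covariate, the fit without libraries under 25000000 counts, thinning, and the estimated correlation for M8 and M9 libraries; the other settings were planned, and the planned pseudocounts were not run because the values are counts. The 3 comparisons and the test among the groups gave 0 genes by edgeR in every setting except the ones named next. At an unadjusted p under 0.05 they gave 1997, 836, 335 and 1068 genes, and over the settings 335 to 3175, 483 to 1277, 203 to 1607 and 349 to 2034. DESeq2 gave 8 genes for multidose against control, 10 for single dose against control and 9 among the groups. A block by replicate number gave 1 for multidose against control (RNF180, 0.94, adjusted p = 0.0236 by edgeR) and 1 among the groups. The labels do not say whether the numbers pair the animals. Of 15 pairs of libraries that share a number, 4 had a correlation above 0.1. For 2 of 15 libraries the most correlated library of another group had the same number. These counts alone do not decide whether there is pairing. The Y-linked covariate and thinning gave 1 each for single dose against control (TSPOAP1). Leaving out each library in turn gave between 0 and 1 genes for single dose against control, for multidose against single dose and among the groups; against control the gene was TSPOAP1 without single dose 2 and ACSM5 without single dose 5, which also gave the call between the dosed groups. Among the groups 1 gene passed without vehicle control 2, vehicle control 5 or single dose 5. Of 27 list calls, 27 were kept with RLE scaling, 23 with thinning and with the Y-linked covariate, 22 with the suffix covariate and with the block, 20 with the M1 covariate, 18 without libraries under 25000000 counts, 17 with M8 and M9 libraries only, and 0 with fry or an estimated correlation, also with M8 and M9 libraries only. At these group sizes edgeR recovered 4.48% to 20.9% of changes simulated at a fold of 1.5. Depth was varied by thinning and by leaving out the shallowest libraries, all of which are M1 libraries.

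The following values, or camera's direction for lists, changed sign, and except where libraries left out carried the value, the cause was not tested. With M8 and M9 libraries only, the natriuretic list after multiple doses turned in direction but not in its median of -0.050 (adjusted p = 0.810, and 0.934 with an estimated correlation), and the immediate early (0.186 and 0.881) and ribosomal (0.400 and 0.881) lists between the dosed groups turned in both; with the M1 covariate the natriuretic (0.389) and ribosomal (0.283) lists turned, and without libraries under 25000000 counts the immediate early list (0.776). The interferon list between the dosed groups turned without multidose 5, and its adjusted p ranged from 2.28e-07 to 0.126 over the libraries left out. For multidose against control, COL3A1 was -0.27 with the name series as covariate, -0.28 with M8 and M9 only and -0.26 with the M1 covariate. PECAM1 was -0.0048 without the low-count filter, -0.0033 with the suffix covariate, -0.20 with the series covariate, -0.25 with M8 and M9 only, -0.051 with the Y-linked covariate, -0.20 with the M1 covariate and -0.021 without libraries under 25000000 counts, and -0.10 to 0.067 with a library left out. ISG15 was -0.46 with _R libraries only, -0.29 with limma-voom and -0.59 to 3.19 with a library left out. For single dose against control, RPL22 was -0.033 and RPS9 -0.032 with _R libraries only, PECAM1 was 0.021 with limma-voom, and with a library left out COL1A1 was -0.15 to 0.25 and VEGFA -0.27 to 0.013. Between the dosed groups, COL3A1 was -0.031 with the suffix, -0.38 with the series and -0.37 with the M1 covariate, -0.39 with M8 and M9 only and -0.080 to 0.39 with a library left out. NPPA was 0.57, 0.59 and 0.63 with these covariates, 0.56 with _R only, 0.77 with M8 and M9 only, 0.40 without libraries under 25000000 counts and -1.33 to 0.39 with a library left out. NPPB was 0.51, 0.98 and 0.99 with the covariates, 0.13 with _R only and 0.23 with M8 and M9 only. PECAM1 was -0.027 with the series covariate, -0.10 with M8 and M9 only and -0.023 with the M1 covariate. MYL1 was -0.26, -0.57 and -0.17 in the same 3 settings, and MARCO was -0.24 with limma-voom. NR4A1 was 0.056 and FOSB 0.29 with M8 and M9 only, and FOSB was 0.058 without libraries under 25000000 counts. ISG15 was -0.65 to 3.75 and IRF7 -0.37 to 2.14 with a library left out, and IRF7 was -0.32 with DESeq2.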

Other observations

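Only the estimated correlation without the M1 libraries was chosen after the results it concerns had been seen, and with all libraries no list named here passed in the comparison given. Against control, the adipocyte list held GPD1 (ENSSSCG00000000214), the glycerol-3-phosphate dehydrogenase gene, at 0.93 (SE 0.31) after multiple doses and 1.23 (SE 0.33) after a single dose, the latter being the 1 of its 13 members that passed adjusted over the list alone, with 0 over all genes. The macrophage scavenger receptor gene MARCO (ENSSSCG00000015716) stood at -3.07 (SE 0.90) after multiple doses and -4.32 (SE 1.10) after a single dose, with 15.7 CPM in vehicle control 1 and values of -1.54 and -2.79 in the same order without that library, and it alone passed adjusted over the macrophage list after a single dose, with 0 over all genes. KIT (ENSSSCG00000008842), a mast cell receptor gene, stood at -0.71 (SE 0.28) and -1.10 (SE 0.31) in the same order (-0.24 and -1.04 without the M1 libraries), and it alone passed adjusted over the neutrophil and mast cell list after a single dose. MYL1 stood at 2.38 (SE 0.61) after multiple doses, the 1 skeletal muscle gene that passed adjusted over its list there, and at 1.01 without the M1 libraries. In the fatty acid oxidation list, CPT1A (ENSSSCG00000012880), the gate of mitochondrial fatty acid import, stood at -0.75 (SE 0.26) after multiple doses and -1.02 (SE 0.28) after a single dose, and PDK4 (ENSSSCG00000015334), a pyruvate dehydrogenase kinase, at -1.94 (SE 0.74) and -2.45 (SE 0.85), with 602 CPM of PDK4 in vehicle control 4 and values of -0.61 and -1.11 in the same order without that library.

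Extracellular matrix genes had medians of -0.06 after multiple doses and -0.05 after a single dose (adjusted p = 0.277 and 0.0516), with THBS1 (ENSSSCG00000004789) at -0.43 (SE 0.15) and COL5A1 (ENSSSCG00000005751) at -0.53 (SE 0.20) after multiple doses. Without the M1 libraries the matrix list passed after multiple doses (median -0.27, adjusted p = 0.000837, preset correlation). So did Schwann and neural markers (median -0.87, adjusted p = 1.54e-07), fibroblast markers (-0.21, adjusted p = 0.0170) and erythroid genes (-1.02, adjusted p = 0.0120), each against 3 multidose libraries. Interferon genes then had a median of 1.19 (adjusted p = 1.35e-08), with multidose 5 among those 3 libraries. In all, 15 lists passed for multidose against control without the M1 libraries, against 10 with them. With an estimated correlation 0 of these lists passed without the M1 libraries (adjusted p = 0.550 for Schwann and neural markers and 0.584 for the other 4 named here).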
